A study of Mus musculus with 4 samples.

How the data were processed

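RNA of E14 mouse embryonic stem cells was sequenced in 4 libraries, 2 from cells transfected with esiRNA against Pnldc1 and 2 from cells transfected with esiRNA against luciferase. Per the labels' protocols, cells were transfected with Lipofectamine RNAiMAX, total RNA was extracted with a column kit, ribosomal RNA and RNA under 200 nt were depleted, and libraries were prepared with an Ion OneTouch template kit, which serves Ion Torrent sequencing. The samples were grouped by their titles. Reads were processed with TopHat and Cuffdiff and the genome builds mm10 and GRCm38.p4, per the submitters' processing notes. Versions, options and the gene annotation are not given in the sources used here.

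The deposited data are 1 Cuffdiff table of gene differences, per the file headers, in which the authors combined the libraries into 2 conditions named q1 and q2. Each of 23922 genes has 1 expression value in each condition, a test status, a test statistic (a signed score, per the file headers), a p-value and an adjusted q-value, all made by the authors. The unit of the deposited values is not stated in the file headers. Cuffdiff gives FPKM by default, and the values were very high for short RNAs, as values per kilobase would be. Neither the labels nor the file headers say which esiRNA q1 or q2 stands for. The comparison of the Pnldc1 esiRNA with the control could therefore not be given a direction, and no condition was assigned from the values, the level of Pnldc1 included. The planned comparison was kept, with differences given as q2 against q1.

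The table had passed through a spreadsheet. In 1055 cells of the deposited log2 fold column the text #NAME? stood in place of a number, so that column was not used and the log2 ratio of the q2 value over the q1 value was computed again. It differed from the readable deposited numbers by at most 1.32e-05. In 17 gene names a comma was turned back into a point. The deposited q-values were checked against a Benjamini-Hochberg adjustment of the deposited p-values over tested genes and differed by at most 5.24e-07. The smallest deposited p-value was 5e-05, shared by 78 genes.

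Sequencing depth is not stated. If the values are FPKM, low values fall in steps worth 1 fragment. Among protein-coding genes of up to 3 steps, 72.5% in q1 and 69.7% in q2 lay within 0.15 of a whole step. Evenly spread values would give 30%, but the step was fitted to these same values, so 30% is not a chance level. The size of the step corresponds to about 1240000 fragments in q1 and 1440000 in q2, as normalised by the authors. On that scale the median tested gene had about 116 and 140.0 read equivalents. These are estimates for whole conditions, and no count test was run on them.

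Since the table holds no values of single libraries, the authors' Cuffdiff test was taken as the test of each gene, at a q under 0.05, as the design written before the data were examined foresaw for such a table. No test of genes, SD, replicate block or leave-one-out fit could be computed from it. For 29 gene lists, also fixed before the data were examined, the members that passed were counted in each direction, over all tested genes and with Benjamini-Hochberg adjustment over the list alone. A two-sided Fisher's exact test set the members that passed against all other tested genes, with Benjamini-Hochberg adjustment over the 27 lists with a tested member. Genes are not independent replicates, so its p-values describe these libraries only. The median log2 ratio of each list with 3 or more values was placed among 10000 random lists of the same size matched in 20 bins of mean value, as a description of these libraries. Genes at 0 in a condition, 65 of the 5719 tested, were left out of medians. The list of mitochondrially encoded genes had no member in the table.

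The genes named in the text follow a rule set before the data were examined: Pnldc1; the 12 genes with the largest ratio in each direction among those that passed, with values above 0 in both conditions and a higher value of at least 1, leaving out predicted models, clone names and small RNAs; up to 4 members of each list, those that passed first; and every tested deadenylase. Small RNA genes (7) and predicted or clone-named genes (7) that passed were counted and not named by that rule. Genes named outside it are marked where they appear, and some that it selects are not reported here.

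Coordinates, transcript lengths and GC content come from the GENCODE M21 annotation of GRCm38, the assembly of mm10, matched by gene symbol with 1 representative transcript per gene. A transcript was found for 5455 of the 5719 tested genes (95.4%). Rank correlations of the log2 ratio with length and GC content were tested with 10000 permutations. For each list, the value that a plane fitted to the 200 protein-coding genes nearest in length and GC content gave was subtracted from each member's ratio. The median of the remainders was placed among 10000 random lists of the same size. Those lists were not matched on mean value and take genes as independent. Their percentiles were not adjusted for the number of lists, so a few can lie beyond the central 95% by chance alone. Copies of ribosomal protein and histone transcripts were counted with BLAST+ 2.17.0 as transcripts of other genes at 95% identity over 50% of the length. Annotated spans of 29 of the 111 named genes with coordinates overlap another gene of the table, and whether counting used strand is not given in the sources used here. Computations used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

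The scripts were tested on simulated data for this comparison. Of 200 genes among 5654 that were given a log2 change of 1.5, 97.5% were recovered, and 4.88% of calls were false. The simulated ratios had normal errors with a known standard error of 0.3, and their p-values were made from it. These shares therefore check the scripts and say nothing about the power or error of the authors' Cuffdiff calls. A simulated list that followed only the length and GC trend had a median excess of 0.06 after the plane was removed, and 1 given a further change of 1 had 1.06. Alternatives tried were other thresholds on q, a minimum value, a minimum fold change, Bonferroni adjustment, pseudocounts, and recentring on the median or the upper quartile of tested genes.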

Results

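RNA was profiled by sequencing in E14 cells, a line of mouse embryonic stem cells that is kept undifferentiated with leukemia inhibitory factor (LIF). Cells were transfected with esiRNA, a pool of short interfering RNAs cut from a long double-stranded RNA, against either Pnldc1 or luciferase, a reporter that mouse cells lack. Pnldc1 encodes a deadenylase of the PARN family, an enzyme that shortens RNA from its 3′ end. There were 2 libraries with the Pnldc1 esiRNA and 2 with the luciferase control, made from total RNA after depletion of ribosomal RNA and of RNA under 200 nt. The question is which genes differ after transfection with the Pnldc1 esiRNA. The values are those of the authors' deposited table, which gives each of 23922 genes 1 expression value in each of 2 conditions, named q1 and q2. The sources used here do not tie q1 or q2 to an esiRNA, so each difference below is given as higher in q2 or higher in q1, and none is a direction of the silencing. The table holds no values of single libraries, so no value below has an SD, and the only measure of replicate error is the authors' Cuffdiff test. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so those p-values speak for these libraries only, whose spread may be technical. How Cuffdiff estimated that spread is not given in the sources used here.

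Pnldc1, the target, had a value of 18.1 in q1 and 26.8 in q2 in the authors' deposited table, and the difference did not pass the authors' test (Cuffdiff p = 0.118, q = 0.399). The log2 ratio of q2 over q1 was 0.56. The gene lies on chromosome 17 from 12888729 to 12910230, on the minus strand (GRCm38). If the values are FPKM, they correspond to about 47.0 read equivalents in q1 and 81.0 in q2, so the gene was measured at low depth. The values do not show which condition received the Pnldc1 esiRNA. Whichever did, the difference was 1.48-fold and did not pass, so the values do not establish that Pnldc1 RNA was reduced.

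The clearest difference between the conditions was in 3 classes of RNA that were higher in q2: replication-dependent histone mRNAs, structural non-coding RNAs and mRNAs of cytosolic ribosomal proteins. Genes higher in q1, small RNA genes aside, were led by Trappc13, Lars2 and Pabpc1 and included Naa35, Naa15 and Eif5b. The values of Trappc13 and Lars2 may not measure the mRNAs alone, as described below. Of the 32 genes of naive and core pluripotency in the table, 29 were tested and Klf2 alone passed the authors' test, and none of the 9 tested catalytic deadenylases other than Pnldc1 passed it. In total 243 of 5719 tested genes (4.25%) passed the authors' test at a q under 0.05, 132 higher in q2 and 111 higher in q1. Changes were small: the median absolute log2 ratio of these genes was 0.83, and 77 differed by 2-fold or more, 57 higher in q2 and 20 higher in q1. At an unadjusted p under 0.05 there were 1074 genes. The authors left 18203 genes untested, and 9029 of the genes in the table were at 0 in both conditions. The log2 ratio of all tested genes had a median of 0.06, and the upper quartiles of the values in q2 and q1 differed by 0.14 on the log2 scale. Of the 243 genes 54.3% were higher in q2, and none had an absolute log2 ratio under 0.49. The histone, ribosomal protein and structural RNA lists held 50 of the 243 genes, all higher in q2. The majority turned when all genes of these lists were left out and q was adjusted again over the remaining genes. With this setting, chosen after the results were seen, 65 genes were higher in q2 and 95 in q1.

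**Figure D1:**
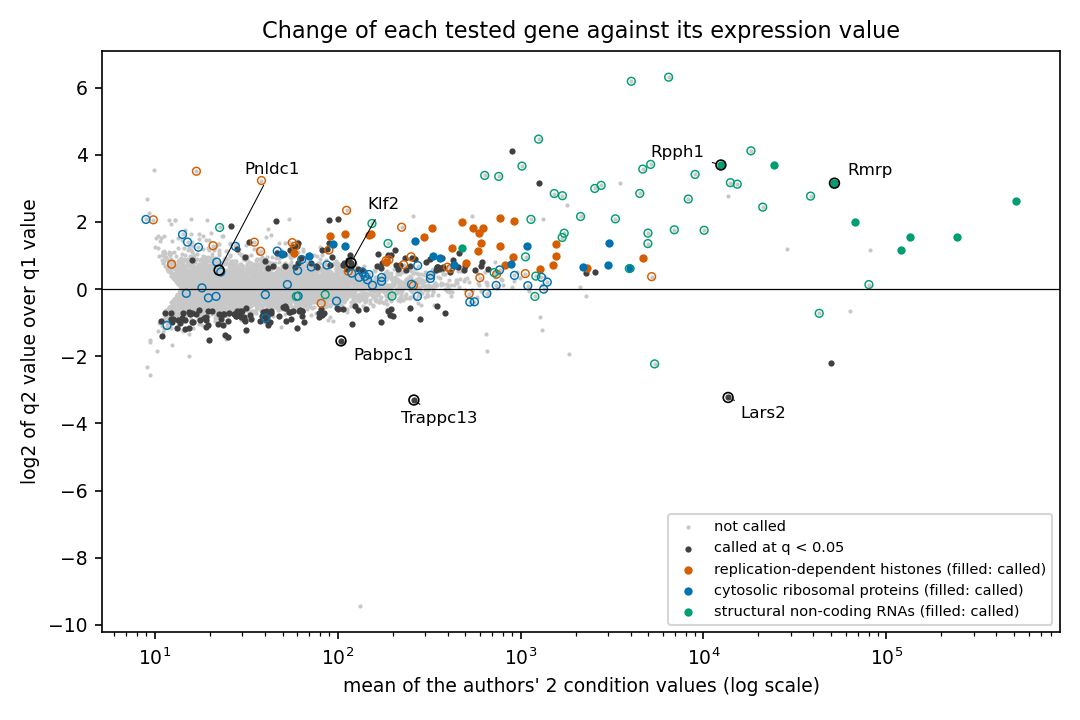
Log2 ratio of the q2 value over the q1 value (y axis) against the mean of the authors' 2 condition values (x axis, log scale) for each tested gene with a value above 0 in both conditions. Grey points did not pass the authors' test at a q under 0.05 and dark points did. Colours mark 3 gene lists, with filled symbols for members that passed. The 27 histone genes that passed lie above 0, while Lars2 at -3.23 and Trappc13 at -3.30 lie far below it. Pnldc1, which did not pass, lies at 0.56.

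Histone mRNAs of the replication-dependent class, which end in a stem-loop rather than a poly(A) tail, were higher in q2 as a group. Of 53 tested genes, 27 were higher in q2 and none was higher in q1 at a q under 0.05, and 39 and 1 were so when adjusted over the list alone. The median log2 ratio was 1.13, above the medians of 10000 random lists matched on expression (percentile 100), and 51 of the 53 lay above 0. It was 0.63 once the trend with transcript length and GC content described further on was removed, a setting chosen after the results were seen. In the authors' deposited table Hist1h3e went from 292.1 in q1 to 1261 in q2 (log2 ratio 2.11), Hist1h4h from 362.6 to 1475 (2.02) and Hist1h2ag from 192.1 to 761.4 (1.99), each with q = 0.00367. Hist1h4a had a log2 ratio of 1.82 (q = 0.0122). All 4 lie in the histone cluster of chromosome 13, Hist1h3e from 23561534 to 23562369, Hist1h4h from 23531050 to 23531519, Hist1h2ag from 22042460 to 22042944 and Hist1h4a from 23760692 to 23761230. Histone genes share sequence with each other, which makes values of single members uncertain. The 21 tested histones with no near-identical transcript of another gene had a median log2 ratio of 1.13, and the 32 with 1 or more had 1.07. Members of the list passed more often than other tested genes (two-sided Fisher's exact test, adjusted p = 2.17e-22 over 27 lists). That test takes genes as independent, which histones that share sequence and come from the same libraries are not.

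Structural non-coding RNAs, the list of small nucleolar, spliceosomal and other short RNAs of the RNA-processing machinery, were also higher in q2. Of 69 tested, 9 passed as higher in q2 and none as higher in q1 (12 and 0 when adjusted over the list alone; Fisher's exact test, adjusted p = 0.0213), and 62 of the 69 had a higher value in q2. The median log2 ratio of the 52 with a value above 0 in both conditions was 2.09 (percentile 100). Rmrp, the RNA of the RNase MRP complex, went from 10509 in q1 to 93681 in q2 in the authors' deposited table (log2 ratio 3.16, q = 0.00367; chromosome 4, 43492783 to 43493063). Rpph1, the RNA of RNase P, went from 1784 to 23147 (3.70, q = 0.00367; chromosome 14, 50807449 to 50807767). The small nucleolar RNAs Snora26 and Snord35a had log2 ratios of 3.69 and 2.62, each with q = 0.00367. Of the 69 RNAs, 62 are annotated as under 200 nt, the length below which RNA was depleted, 16 were listed at 0 in q1 and 1 at 0 in q2. If the values are per kilobase, a given number of reads makes a larger value for an RNA this short, and the values of these 62 describe what was left after the depletion. Rmrp and Rpph1, at 281 and 319 nt, are longer than that limit.

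Ribosomal protein mRNAs were higher in q2 by a smaller amount. Of 60 tested, 14 were higher in q2 and none in q1 (18 and 1 when adjusted over the list alone; Fisher's exact test, adjusted p = 1.76e-06). The median log2 ratio was 0.46 (percentile 99.99), or 0.32 after recentring on the upper quartiles and 0.21 with the length and GC trend removed. Rpl41 went from 1710 in q1 to 4416 in q2 in the authors' deposited table (log2 ratio 1.37, q = 0.00367), Rpsa from 143.5 to 386.7 (1.43, q = 0.00367), and Rps19 from 63.4 to 155.5 (1.29, q = 0.0300). Rpl7a had a log2 ratio of 1.34 (q = 0.00802). Rpsa contains the small nucleolar RNA gene Snora62. Rpl7a has 35 near-identical transcripts of other genes, Rps19 has 6 and Rpl41 has 1, so the values of these genes are uncertain. Across the 60 tested genes the log2 ratio showed no clear relation to the number of such copies (Spearman's rho = 0.13, permutation p = 0.304). Of 84 ribosomal protein genes, 24 were not tested, and the highest value among them was 12.0. The counts and medians therefore describe the tested members only. Translation factors moved in both directions. Of 52 tested, 3 were higher in q2 and 4 in q1 (5 and 7 when adjusted over the list alone; Fisher's exact test, adjusted p = 0.0404, which became 0.106 at a q under 0.01). Eif6, which keeps the ribosomal subunits apart, had a log2 ratio of 1.03. Eif5b, which joins the subunits, had -1.15, and Eif3f, a subunit of eIF3, had -0.94. The other genes that passed, chosen for mention after their values were seen, were Eef1b2 (0.67) and the translation repressor Eif4ebp1 (0.61) on the q2 side and Abce1 (-0.51) on the q1 side. The remaining one was Pabpc1.

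**Figure D2:**
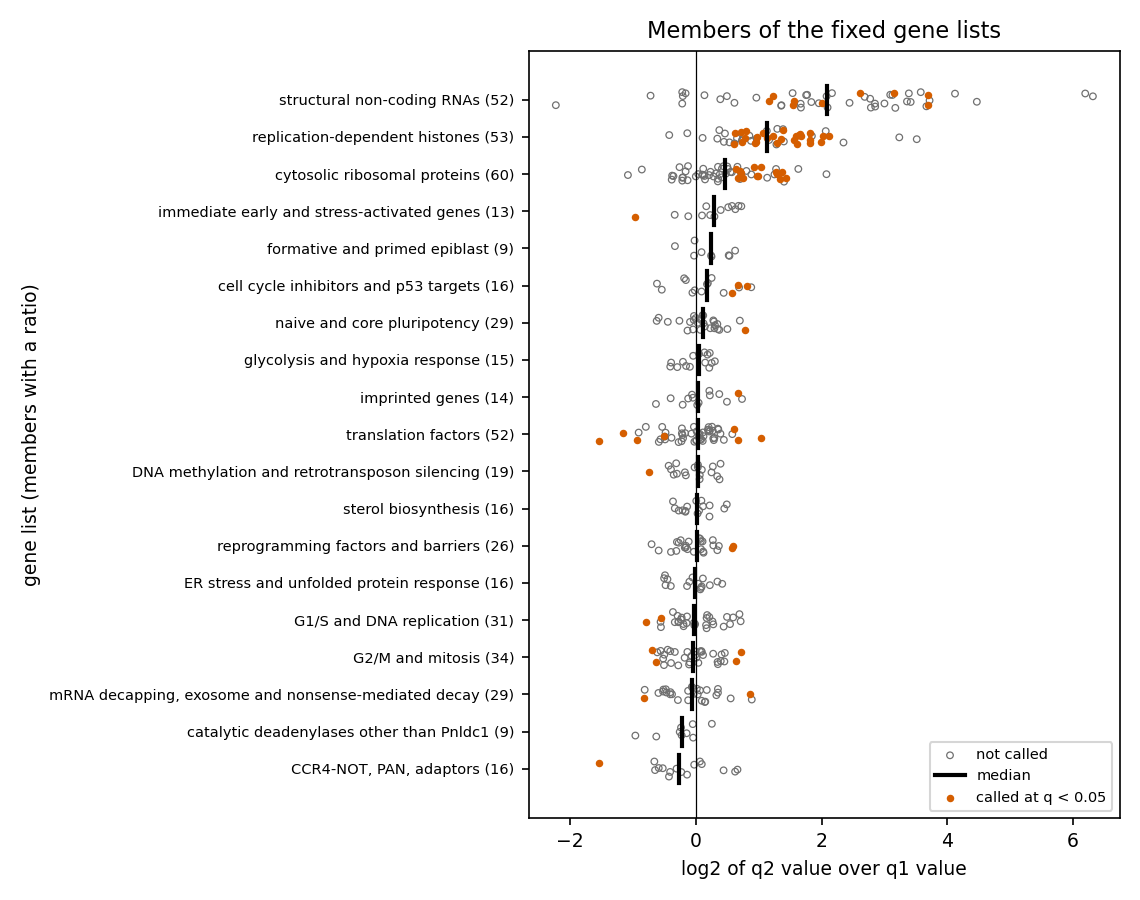
Log2 ratio of the q2 value over the q1 value (x axis) for the members of each fixed gene list with at least 9 tested members (y axis, with the number of members that have a ratio). Filled symbols passed the authors' test at a q under 0.05, open symbols did not, and bars are list medians. The medians of structural RNAs (2.09), histones (1.13) and ribosomal proteins (0.46) are the 3 highest, and the lowest, at -0.27, is that of the deadenylation cofactors.

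The genes that passed with the largest difference toward q1 were Trappc13, a subunit of a vesicle-tethering complex, and Lars2, the mitochondrial leucyl-tRNA synthetase. In the authors' deposited table Trappc13 had 474.2 in q1 and 48.0 in q2 (9.88-fold, log2 ratio -3.30, q = 0.00367; chromosome 13, 104142149 to 104178469), and Lars2 had 24673 and 2633 (9.37-fold, log2 ratio -3.23, q = 0.00367; chromosome 9, 123366927 to 123462666). Whether reads of ribosomal RNA contribute to the values of these genes was not tested, so they may not measure the mRNAs alone. Next among protein-coding genes came Pabpc1, the main cytoplasmic poly(A)-binding protein, with 155.3 and 53.3 (log2 ratio -1.54, q = 0.00367; chromosome 15, 36595661 to 36609668). Srrm1, a splicing coactivator, had -1.53, Trim59 -1.43 and Ppp2r2a, a regulatory subunit of protein phosphatase 2A, -1.41. The N-terminal acetyltransferase subunits Naa35 and Naa15 had -1.38 and -1.23. Vkorc1l1 had -1.18, Uba6, a ubiquitin-activating enzyme, -1.16 and Cltc, the clathrin heavy chain, -1.14. Besides the histones, Rpph1 and Rmrp, the 12 genes with the largest differences toward q2 under the naming rule included the RNase P RNA-like gene Rprl3 (98.7 and 1701, log2 ratio 4.11, q = 0.0263), Dancr (2.08), Tmem147 (2.04) and Tysnd1, a peroxisomal protease (1.88). Dancr contains Snora26 on the same strand, so reads of the 2 genes cannot be fully separated. Hist1h2bh (1.82) and Hist1h4f (1.81) were also among the 12.

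No other deadenylase, the class Pnldc1 belongs to, passed the authors' test. With 4.25% of all tested genes passing, a list of 9 need not hold any. Of the 9 tested members other than Pnldc1, 0 passed the Cuffdiff test, and 2 had an unadjusted p under 0.05: Cnot7, a catalytic subunit of CCR4-NOT, with 18.9 in q1 and 9.69 in q2 in the authors' deposited table (log2 ratio -0.96, q = 0.213) and Cnot6 with 24.0 and 15.5 (-0.63, q = 0.258). The other 7 had log2 ratios of -0.26 for Parn, -0.24 for Cnot8, -0.23 for Pan2, -0.15 for Ccrn4l, -0.05 for Toe1, -0.04 for Angel2 and 0.25 for Pde12. The list median was -0.23 (percentile 9.06). Of 16 tested cofactors (CCR4-NOT and PAN subunits and deadenylation adaptors), Pabpc1 alone passed, as higher in q1, and 3 were higher in q1 and 1 in q2 when adjusted over the list alone. Their median log2 ratio of -0.27 lay at percentile 0.72 of random lists, and with the length and GC trend removed it was -0.15, at percentile 4.58 and within the central 95%. Cnot1, the scaffold of CCR4-NOT, had -0.31 (q = 0.262), Cnot10 0.06 and Rqcd1 -0.03. Of 29 tested genes of decapping, the exosome and nonsense-mediated decay, Ddx6, a helicase that promotes decapping, was higher in q1 (52.2 and 29.5, log2 ratio -0.83, q = 0.00367) and Exosc5, an exosome subunit, was higher in q2 (81.9 and 149.3, 0.87, q = 0.0255), as listed in the authors' deposited table. Lsm3 (0.55) and Lsm4 (0.35) did not pass. Of 20 piRNA pathway genes in the table, Tdrd12 alone was tested (24.2 in q1 and 31.7 in q2, q = 0.534), and no other member exceeded 6.37.

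Few markers of stem cell identity passed the authors' test, but Fisher's exact test set none of their lists apart from other tested genes. Of all tested genes 4.25% passed. Klf2, a transcription factor of naive pluripotency, was higher in q2 (87.0 and 149.7 in the authors' deposited table, log2 ratio 0.78, q = 0.00608; chromosome 8, 72319033 to 72321656), and the other 28 tested members of its list did not pass. Pou5f1 had 713.9 in q1 and 864.9 in q2 in the authors' deposited table (log2 ratio 0.28, q = 0.315), Dppa5a had a log2 ratio of 0.35 (q = 0.256), Trim28 0.03 and Nanog -0.13 (q = 0.707). The sign of Trim28 turned when the ratios were recentred on the median of all genes. The list median was 0.11 (percentile 39.7), and -0.03 after recentring on the upper quartiles. Of 26 tested reprogramming factors and barriers, Epcam, an adhesion molecule (0.59, q = 0.0464), and Trp53 passed as higher in q2. None of the 9 tested genes of the formative and primed epiblast passed the Cuffdiff test and 3 had an unadjusted p under 0.05, with log2 ratios of 0.53 for Nodal (q = 0.147), 0.52 for Tead2 (q = 0.0858), 0.25 for Dnmt3b and -0.03 for Lefty1.

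Lineage markers were mostly below the level the authors tested, and no tested member passed. Bmp4 was the 1 tested gene of 23 for mesoderm and definitive endoderm (log2 ratio 0.13), Tfap2c the 1 of 15 for trophectoderm (-0.31), and Tubb3 (0.14) and Stmn2 (-0.21) the 2 of 20 for neuroectoderm. The 4 tested genes of primitive and extra-embryonic endoderm were the laminins Lamc1 (0.05), Lamb1 (0.20) and Lama1 (-0.02) and Sparc (-0.13). Among fibroblast markers 4 of 15 were tested, Vim (0.33), Fn1 (0.05), Timp1 (0.73) and Lgals1, whose values of 18.7 in q1 and 64.8 in q2 in the authors' deposited table gave a log2 ratio of 1.79 and q = 0.0562. None of the 4 passed over all tested genes, 1 passed when adjusted over the list alone, and their median of 0.53 lay at percentile 98.6, or 0.31 at percentile 95.8, within the central 95%, with the length and GC trend removed. Of 25 germline and meiosis genes 4 were tested, Tex19.1 (-0.10), Rhox5 (0.05), Stag3 (-0.30) and Dnd1 (-0.03). None of the 23 genes of the 2-cell-like state in the table was tested, and their highest value was 1.24. The signs of Fn1, Lamc1 and Rhox5 turned on recentring to the median.

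Cell cycle genes moved both ways. In the list for mitosis, Cdc20 and Ube2c, which work with the anaphase-promoting complex, were higher in q2 (log2 ratios 0.63, q = 0.0204, and 0.71, q = 0.0255), while Mki67 and Top2a were higher in q1 (-0.71 and -0.63, each q = 0.00367), with 30 of 34 tested members not passing (Fisher's exact test, adjusted p = 0.244). For DNA replication, the licensing factor Cdt1 (-0.80, q = 0.0300) and Mcm10 (-0.55, q = 0.0418) were higher in q1, and 29 of 31 did not pass, Cdk4 (0.44, q = 0.0894) and Mcm5 (0.16) among them. When adjusted over the list alone, 2 mitosis genes were higher in q2 and 4 in q1, and 4 replication genes in q2 and 3 in q1. Among cell cycle inhibitors and p53 targets, Bax, a pro-apoptotic protein (220.5 in q1 and 387.4 in q2 in the authors' deposited table, log2 ratio 0.81, q = 0.00608), Cdkn1c, an inhibitor of cyclin-dependent kinases (0.68, q = 0.0464), and Trp53 itself (0.58, q = 0.0104) were higher in q2. The list of 16 tested genes did not pass as a group (Fisher's exact test, adjusted p = 0.152), and Aen had 0.25. The list median was 0.18 (percentile 86.9). With the length and GC trend removed it was 0.25 at percentile 99.75, beyond the central 95% but not adjusted for the number of lists.

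Stress, silencing and metabolic lists held at most 1 gene each that passed. Fisher's exact test set none of these lists apart from other tested genes, and 4.25% of all tested genes passed. Hsph1, a heat shock protein, was higher in q1 (87.0 and 44.4 in the authors' deposited table, log2 ratio -0.97, q = 0.00367) and was the 1 of 13 tested immediate early and stress genes to pass, while Hmox1 had 0.57 (q = 0.0819), Hspb1 0.51 and Ier2 0.16. Atrx, a chromatin remodeller, was higher in q1 (-0.75, q = 0.00802) and was the 1 of 19 tested genes of DNA methylation and retrotransposon silencing to pass, with Dnmt3l at 0.34 (q = 0.238) and Uhrf1 at 0.06. Of 14 tested imprinted genes, Cdkn1c alone passed, and Phlda2 had 0.49, Peg10 0.02 and Impact -0.21. The imprinted list had a median of 0.03 (percentile 36.3). With the length and GC trend removed it was 0.20 at percentile 98, beyond the central 95% but not adjusted for the number of lists. No member passed the Cuffdiff test among 16 tested genes of ER stress, 3 of the interferon response, 16 of sterol synthesis and 15 of glycolysis and hypoxia, where 3, 0, 1 and 1 had an unadjusted p under 0.05. Hsp90b1 (-0.48, q = 0.0531) and Canx (-0.45, q = 0.0620) came nearest in the ER list, and both passed when adjusted over the list alone. Hspa5 had 0.07 and Calr -0.05. In the interferon list, whose genes respond to double-stranded RNA, Bst2 had 0.47, Ifitm3 -0.69 and Adar -0.30, and no untested member exceeded 12.2. In the sterol list Hmgcs1 had -0.36 and Srebf2 0.22. Aldoa had 0.25, Tpi1 0.22, Ldha 0.14 and Pkm 0.05. The signs of Peg10 and Pkm turned on recentring to the median.

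Differences followed the length and base composition of transcripts. Among 5146 tested protein-coding genes outside the histone, ribosomal protein and structural RNA lists, the log2 ratio fell with transcript length (Spearman's rho = -0.39 across genes) and rose with GC content (rho = 0.47). The permutation p was 0.0001 for each, the smallest that 10000 permutations can give, and genes are not independent replicates. The 515 genes with the shortest transcripts, with a median length of 901 nt, had a median log2 ratio of 0.33, with 20 genes higher in q2 and 1 in q1 at a q under 0.05. The 515 with the longest, with a median of 7391 nt, had -0.21, with 2 and 42. The 515 genes lowest in GC content had -0.32 at a median of 41.0%, and the 515 highest had 0.29 at 59.8%. Histones (median length 530 nt) and ribosomal proteins (925.5 nt) are short, and Mki67, Atrx, Uba6 and Cltc, which were higher in q1, have transcripts of 10061, 10275, 6590 and 6519 nt.

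**Figure D3:**
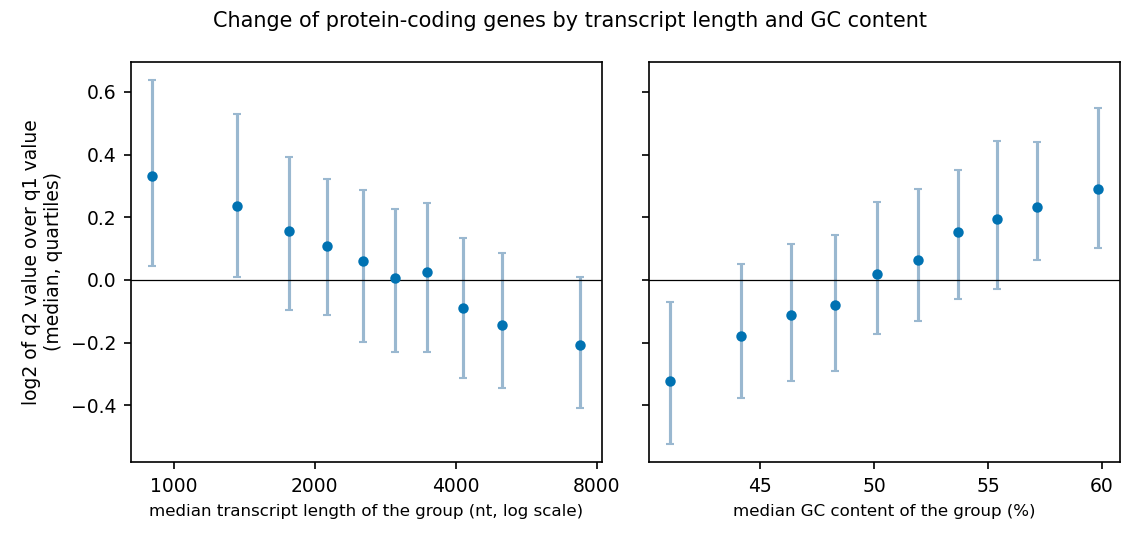
Median log2 ratio of the q2 value over the q1 value (points, y axis) with quartiles (bars) of 5146 tested protein-coding genes in 10 groups of nearly equal size by transcript length (left, in nt, log scale) and by GC content (right, in percent). Histones, ribosomal proteins and structural RNAs are left out. The median goes from 0.33 in the group with the shortest transcripts to -0.21 in that with the longest, and from -0.32 to 0.29 between the lowest and highest GC content.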

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

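The removal of the length and GC trend, the exclusions of short transcripts and of the 3 leading RNA classes and, for named genes, recentring on the upper quartiles were chosen only after the results were seen; the other settings were planned. The number of genes that passed was 107 at a q under 0.01 (65 higher in q2, 42 in q1), 421 at a q under 0.1 (237 and 184), and 77 with an absolute log2 ratio of at least 1 (57 and 20). It was 0 with Bonferroni adjustment (0 and 0), since the smallest deposited p-value, 5e-05, cannot pass that threshold over 5719 genes. Without transcripts under 1000 nt it was 157, with 63 higher in q2 and 94 in q1. Without histones, ribosomal proteins and structural RNAs it was 160, with 65 higher in q2 and 95 in q1. In both cases fewer genes were tested and q was adjusted again over them, so genes outside the excluded sets also lost their call. A minimum value of 1 or 5 left 243, and without genes at 0 in a condition 242 passed. Only 4 translation factors passed at a q under 0.01, and the list no longer did (Fisher's exact test, adjusted p = 0.106). With the length and GC trend removed, list medians moved to 0.63 for histones, 0.21 for ribosomal proteins, 0.10 for immediate early and stress genes and -0.32 for the 4 germline genes, because genes of like length and composition differ between the conditions. Of 112 named genes other than Pnldc1, 6 that did not pass changed sign on recentring on the median, a shift of 0.06, and 11 on recentring on the upper quartiles, a shift of 0.14 (the same 6 and Bmp4, Cnot10, Hspa5, Ldha and Uhrf1). Each follows from a ratio smaller than the shift, and the smallest absolute log2 ratio of a gene that passed was 0.49. Pnldc1 stayed between 0.51 and 0.56 with pseudocounts of 1 and 0.1 and after recentring. No paired analysis was possible because the table has no values of single libraries, although replicate numbers 1 and 2 occur in both groups. For the same reason leaving out each replicate, a replicate block and DESeq2 or tests on values of each library could not be run. No row of the table held several gene symbols, so that setting left all counts as they were. Depth limits what low genes can show: the genes the authors left untested have no call in either direction.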

Other observations

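Except for that of near-identical copies, all tests described in this part were chosen only after the results were seen. The counts and the median, before trend removal, of the fixed list of G1/S and DNA replication were planned. They were set against the histones only afterwards. Gene groups outside the fixed lists were looked at in 6 further lists. The 20 tested genes of cohesin and condensin, the ring complexes that organise chromosomes, and of their loaders and regulators held 5 that were higher in q1 and none higher in q2 (Smc3 -1.08, Pds5b -1.01, Smc4 -0.90, Smc2 -0.72 and Wapal -0.67), and their median log2 ratio was -0.33. Of 9 tested N-terminal acetyltransferase genes, 3 were higher in q1, Naa35, Naa15 and Naa50 (-0.99). Fisher's exact tests gave adjusted p = 0.00731 and 0.0158 for these lists, but the lists were drawn up because such genes had been seen among those that passed, so the tests are not independent evidence. Of 17 tested heterogeneous nuclear ribonucleoproteins, Hnrnpd (-1.07) and Hnrnpa2b1 (-0.78) were higher in q1. Nuclear genes for mitochondrial proteins leaned toward q2: 55 of 68 genes with symbols of the respiratory chain and ATP synthase, a few assembly factors included, and 54 of 69 mitochondrial ribosomal proteins had a higher value there (medians 0.29 and 0.30), but the share that passed did not pass the test against other genes (Fisher's exact test, adjusted p = 0.319 and 0.922). Of these, Uqcrq (1.09), Ndufa8, Cox6b1 (1.00), Ndufb8 (0.88), Mrpl14 (1.37), Mrps34 (1.16) and Mrpl12 (1.02) passed, as did Atp5g3 in the opposite direction (-0.70). Of 35 genes with symbols of the proteasome series, which include Psmc3ip, a recombination factor, and assembly chaperones, Psma7 (0.69) passed. After removal of the length and GC trend, medians of -0.08 for the cohesin and condensin list and 0.04 for the respiratory chain lay within the central 95% of random lists, while that of mitochondrial ribosomal proteins (0.13) lay at percentile 99.8.

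Short, GC-rich protein-coding genes were higher in q2 and long, AT-rich ones in q1. A limited set of strongly changed genes is argued against, since without genes at a p under 0.05 rho was still 0.38 with GC content and -0.29 with length. Length alone is argued against as well, because the partial rank correlation with GC content at fixed length was 0.41. Whether the trend comes from the esiRNAs or from a difference in fragmentation, amplification or RNA quality between library preparations cannot be told apart, since 0 columns of the table hold values of a single library and q1 and q2 are not tied to an esiRNA. Such a difference in preparation may therefore lie behind part of the differences of single long or short genes, Cltc, Uba6 and Atrx among them.

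Histones and ribosomal proteins were higher in q2 by more than the length and GC trend fitted to other protein-coding genes gave. For histones the median excess over the length and GC trend was 0.63, and for ribosomal proteins 0.21, each at percentile 100 of random lists. Those lists were drawn from genes of all lengths. The median histone transcript has 530 nt, while the 515 other genes with the shortest transcripts have a median of 901 nt. For histones the fit may rest largely on longer genes, so a trend that steepens among the shortest cannot be told from an excess. For ribosomal proteins, at a median of 925.5 nt, other genes of like length were in the fit. The random lists were not matched on expression, though, and they take genes as independent. Among other short lists, mitochondrial ribosomal proteins (1288 nt) also lay high, with 0.13 at percentile 99.8. The respiratory chain list (838 nt) did not, with 0.04 at percentile 82.2. Whether the trend of other genes is the whole cause for ribosomal proteins therefore stays open. Better recovery in q2 of all RNA without a poly(A) tail stays open. Malat1 and the long form of Neat1 have no ordinary tail, and these genes had a median log2 ratio of -0.38. Neither passed the authors' test (q = 0.106 and 0.553), and both are long, like the genes that lay lower in q2. The short structural RNAs were higher in q2. A better yield of short RNA, which the structural RNAs and the depletion of RNA under 200 nt make a candidate explanation, also stays open and untested, as does the effect of the esiRNA. A larger share of q2 cells in S phase, when these histones are made, gets no clear support from the fixed list of genes of G1/S and DNA replication, which moved both ways. Its 31 tested members had a median log2 ratio of -0.03 (-0.07 with the length and GC trend removed), and 13 lay higher in q2 and 18 lower. The only ones to pass over all tested genes, Cdt1 (-0.80) and Mcm10 (-0.55), were higher in q1. When adjusted over the list alone, 4 were higher in q2 and 3 in q1, and at an unadjusted p under 0.05, 6 and 5. Not every member need rise with the histones, since the list also holds genes of G1, so this explanation stays open.

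Some genes that every cell uses were listed at or near 0: Gapdh had 5.90 in q1 and 11.2 in q2, Ppia 0 in both and Rpl10 and Rpl29 0 in both, in the authors' deposited table. Reads shared with near-identical copies could cause this, and Gapdh has 67 such transcripts of other genes, Rpl29 23 and Rpl10 9. Over 84 ribosomal protein genes the value fell with the number of copies by Spearman's rho = -0.21 (permutation p = 0.0563; Pearson's r = -0.22 on log2 values), which leaves it open. The 9 genes with 10 or more copies had a median value of 9.88 and the 75 others 63.6. Ppia has 1 such copy, so copies alone need not account for every such gene.

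Of the genes that passed, 1 was listed at 0 in a condition: Smim4, with 0 in q1 and 38.9 in q2 (q = 0.00608) in the authors' deposited table. Mir6236, a small RNA gene, had 81549 in q1 and 17905 in q2 (log2 ratio -2.19, q = 0.00367), in the same direction as Lars2 and Trappc13. Whether reads of ribosomal RNA contribute to its values was not tested either. Among other widely used reference genes, Actb was higher in q2 (0.49, q = 0.0321), and Eef1a1 (0.05), Eef2 (0.36), Hprt (-0.33) and Tbp (0.53) did not pass. These genes were chosen after their values were seen.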
